A study of Homo sapiens with 4 samples.

How the data were processed

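RNA from KBM5 cells, a human cell line from a patient with BCR-ABL-positive chronic myeloid leukemia in blast phase, was sequenced in 4 libraries, labelled CTR, DSF, IM and IM-DSF, with a stranded mRNA kit per the labels' protocols. The labels give 1 library per group and no dose or time. They do not spell out the abbreviations; IM and DSF are read here as imatinib, a BCR-ABL kinase inhibitor, and disulfiram, and the codes of the labels are kept throughout.

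The authors deposited 1 table of FPKM (fragments per kilobase of gene, scaled to library depth) for 50868 genes, with 4 value columns named after the samples, per the file headers. HISAT2 2.0.4 and the build GRCh38.p14 are named in the submitters' processing notes. The read counter, the annotation release, the gene lengths, the use of strand in counting and any further scaling are not given in the sources used here. Gene coordinates are those of the deposited table. GENCODE 29 matched 50111 of the gene identifiers and gave biotypes, exon lengths and same-strand overlaps, and 47538 genes had the same start and end in it.

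The depth was recovered in part. In single-exon genes, FPKM multiplied by gene length was a whole multiple of 1 step per library, within 0.05 of a whole number, for 97.9% of 3458 genes in CTR, 93.7% of 3521 in DSF, 96.8% of 3602 in IM and 97.5% of 3474 in IM-DSF. The steps correspond to denominators of 14.5 M, 14.7 M, 15.8 M and 12.4 M fragments, where M is 1e+06. Across genes with several exons only 19.6% of the CTR values were whole under the exon lengths used here, so no count test was run. Approximate fragment numbers from these lengths give the 95% intervals of fold differences (exact conditional binomial). A fold is the ratio of 2 deposited FPKM values. The intervals cover counting error only, not the spread between cultures, and PCR copies make them too narrow.

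Differences were computed as log2(FPKM + 1), which understates the change of low genes, for 11004 genes with a mean of at least 1 FPKM over the 4 libraries, 9365 of them protein-coding. With 1 library per group there is no replicate check, and no p-value is given. A gene is called higher or lower by a size rule of at least 1 log2 unit (2-fold on that scale). The contrasts were DSF, IM and IM-DSF against CTR, IM-DSF against IM, and IM-DSF against DSF. The departure from additivity is the IM-DSF difference from CTR minus the sum of both single-drug differences. DSF against CTR and IM-DSF against IM share no library, and neither do IM against CTR and IM-DSF against DSF, so genes called in both contrasts of such a pair were counted beside the number that independent lists would share.

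The 29 gene lists, the contrasts, the size rule and the rule for named genes were fixed before the data were examined. For each list with at least 5 members past the filter (26 lists), the median log2 difference was placed among the medians of 10000 random lists of protein-coding genes of the same size, matched on mean expression in 20 bins. A list stands apart when its median lies outside the central 95% of these, which describes these libraries and tests no condition. The lists are ferroptosis, glutathione, NRF2 targets, metal response, copper handling, heat shock, the ATF4 integrated stress response, endoplasmic reticulum chaperones, proteasome, STAT5 targets, ERK targets, MYC targets of ribosome biogenesis, G1/S, G2/M, p53 targets, BCL2 family, cholesterol, glycolysis, mitochondrially encoded genes, ribosomal proteins, histones, erythroid, granulocyte and monocyte, megakaryocyte, lymphoid and stem cell markers, NF-kB targets, interferon-stimulated genes, and autophagy and lysosome genes. 1 list symbol matched no gene.

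The named genes are GPX4, BCR and ABL1; for each drug, up to 10 genes per direction past the size rule in both contrasts of its pair, ranked by the smaller difference; the 10 highest and 10 lowest in IM-DSF against CTR; the 5 most positive and 5 most negative departures; and up to 4 members per list with the largest difference in the contrast described. Pseudogenes and genes with clone-style names were left out of the naming. Genes that overlap another gene on the same strand are reported as uncertain, since it is not known how the counting divided their reads. Overlap on the opposite strand was not marked. Near-identical copies raise the same doubt but were not marked gene by gene. They are mentioned only for ribosomal proteins, metallothioneins and RN7SL1, so other named genes may have them too.

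Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, rescaling to TPM, median-of-ratios factors, and trimmed-mean factors, all planned. Chosen after seeing the data were a restriction to protein-coding genes without same-strand overlap and, for the lists, each gene summed with its pseudogenes. The size rule was tested on simulated libraries of 10962 genes with counting noise, in which 200 genes per contrast were changed by known folds. In DSF against CTR it recovered 85.1% of genes changed 3-fold, 86.6% changed 4-fold and 97.0% changed 8-fold, and in IM-DSF against CTR 73.1%, 85.1% and 95.5%, with 0 genes called in the wrong direction in any contrast. In these simulations counting noise alone led to 4 to 8 calls per contrast among 10762 unchanged genes. All 5 shifted simulated lists, whose members were all raised 3-fold to 8-fold, lay above the central range, and 4 of 5 unshifted lists lay inside it. No list median in the results reached even the size rule, and the simulated genes did not vary together. The simulated lists therefore do not show how often shifts of the reported size are found or called wrongly. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.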

Results

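Gene expression was measured by mRNA sequencing in KBM5 chronic myeloid leukemia cells that were untreated (CTR) or treated with DSF, IM or both (IM-DSF), with 1 library for each of the 4 groups. According to its title, the study asked what joint targeting of the lipid peroxide reductase GPX4 and the BCR-ABL kinase does to BCR-ABL-positive leukemia stem cells. The deposited FPKM values summed to 278558 in CTR, 285146 in DSF, 287546 in IM and 277648 in IM-DSF, with denominators of 14.5 M, 14.7 M, 15.8 M and 12.4 M fragments (M is 1e+06). Between 10677 (CTR) and 11238 (IM-DSF) genes reached 1 FPKM. There were no replicates, so each difference below is between 2 libraries and carries no p-value, and its interval covers counting error only. Mitochondrial genes held 30.1% (IM) to 32.6% (DSF) of the summed FPKM. Across genes, the log2 values of CTR correlated with those of DSF at r = 0.981, of IM at 0.965 and of IM-DSF at 0.951; genes are not independent replicates.

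None of the genes named in the study's title passed the size rule of 1 log2 unit in any contrast. GPX4 (ENSG00000167468; GRCh38.p14 chromosome 19, 1103926 to 1106791), which reduces lipid hydroperoxides with glutathione, had 19.6 FPKM in CTR, 20.1 in DSF, 19.7 in IM and 17.6 in IM-DSF. The ratio of IM-DSF to CTR was 0.898 (95% interval 0.792 to 1.02), which includes 1, and that of IM-DSF to DSF was 0.877 (0.774 to 0.993), which does not. ABL1 (chromosome 9, 130713946 to 130887675), the kinase part of the fusion, had 34.0, 34.7, 35.1 and 34.0 FPKM in the same order. BCR (chromosome 22, 23179704 to 23318037), its fusion partner, had 4.22, 4.16, 3.99 and 5.93 FPKM, and was 1.41 times CTR (1.28 to 1.55) and 1.49 times IM (1.35 to 1.64) in IM-DSF. It overlaps other genes, and gene-level values do not separate the fusion transcript from the normal alleles.

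IM against CTR asks what the kinase inhibitor alone left different, and IM-DSF against DSF asks the same in cells that also received DSF. Genes of myeloid differentiation and the lysosome were higher with IM in both contrasts. LYZ, the lysozyme of granulocytes and monocytes, had 154 FPKM in CTR and 399 in IM (2.59-fold, 95% interval 2.49 to 2.68), and 217 in DSF and 599 in IM-DSF (2.76-fold, 2.68 to 2.85). CSF3R, the receptor for granulocyte colony-stimulating factor, was 3.61-fold higher in IM (3.30 to 3.95) and 2.33-fold higher in IM-DSF than in DSF (2.17 to 2.50). MS4A6A, a membrane protein of monocytes, was 6.25-fold higher (4.93 to 8.04) and 3.35-fold higher (2.89 to 3.91). The lysosomal enzymes FUCA1 (a fucosidase; 8.89 FPKM in CTR, 22.7 in IM, 42.3 in IM-DSF), DNASE2 (1.75, 5.91 and 13.1 FPKM) and CTSO (1.42, 4.71 and 6.91 FPKM) had the same order. TP53INP1, a stress-induced p53 target, was 5.60-fold higher in IM (4.53 to 7.04) and 4.18-fold higher in IM-DSF than in DSF (3.55 to 4.99). AOAH, which deacylates lipopolysaccharide, UBA7, the activating enzyme for ISG15, and TRAPPC6A, a vesicle-tethering subunit, completed the 10 named genes, with log2 differences in IM of 1.81, 1.22 and 1.34. AOAH and UBA7 overlap another gene, and TRAPPC6A had only 0.50 FPKM in CTR.

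The 10 named genes that were lower with IM in both contrasts had varied functions. PIM1, a survival kinase transcribed downstream of STAT5, had 16.0 FPKM in CTR, 4.67 in IM, 8.18 in DSF and 2.63 in IM-DSF. ID1, an inhibitor of differentiation, was 0.400 times the CTR level in IM (0.296 to 0.547) and 0.299 times the DSF level in IM-DSF (0.191 to 0.468). SLC7A5, a large neutral amino acid transporter, had 69.7 FPKM in CTR and 22.4 in IM. GLO1, the glyoxalase that detoxifies methylglyoxal, had 93.3 and 34.3 FPKM, and PSME3, a proteasome activator subunit, had 13.9 and 4.57 FPKM. JPT2 (11.3 and 2.27 FPKM), the zinc finger gene ZNF184 (7.11 and 1.81) and ERI1, an exoribonuclease that acts on histone mRNA (6.34 and 2.31), were also among the 10. The read-through genes SENP3-EIF4A1 (29.6 and 9.24 FPKM) and STON1-GTF2A1L (4.36 FPKM in CTR, listed at 0 in IM and IM-DSF) share exons with their neighbours, so their values are uncertain, as are those of the overlapping genes JPT2, SLC7A5 and ERI1.

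By the size rule, 169 genes were higher and 98 lower in IM than in CTR, and 146 were higher and 115 lower in IM-DSF than in DSF. Of these, 34 were higher in both contrasts and 19 lower in both, where independent lists would share 2.24 and 1.02, and 16 went in opposite directions. The 2 sets of log2 differences, which share no library, correlated across genes at Pearson's r = 0.43 and Spearman's rho = 0.53; genes are not independent replicates.

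**Figure D1:**
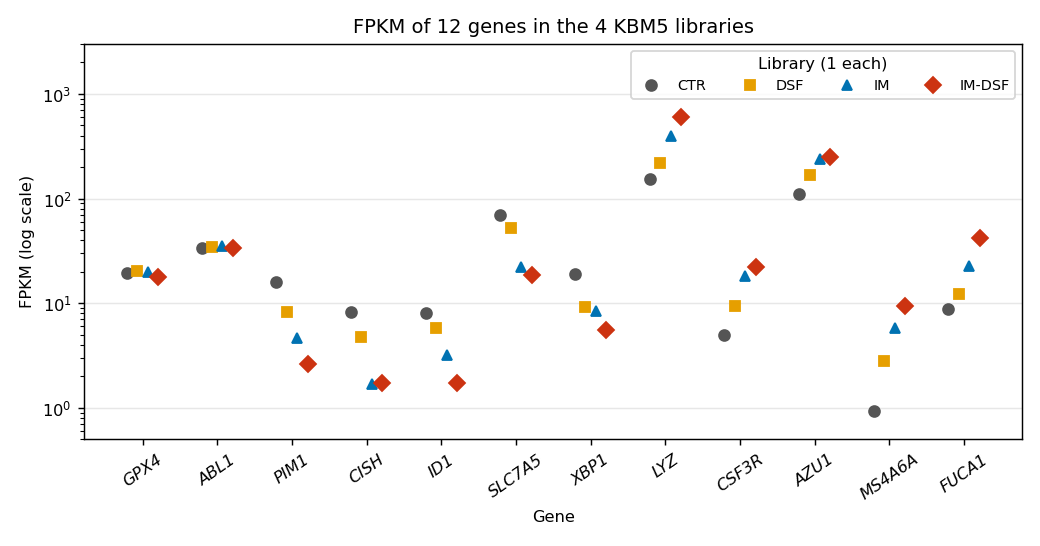
FPKM (vertical axis, log scale) of 12 genes (horizontal axis) in the CTR, DSF, IM and IM-DSF libraries, 1 point per library with no error bar since there were no replicates. GPX4 lay between 17.6 and 20.1 FPKM, PIM1 between 2.63 and 16.0, and LYZ between 154 and 599.

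Target genes of the pathways that BCR-ABL drives were lower with IM as groups. Of 12 measured STAT5 targets, 11 lay below CTR in IM and 3 passed the size rule, with a list median of -0.29 log2 units (central 95% of matched random lists -0.17 to 0.24). CISH, a feedback inhibitor of cytokine signalling, had 8.18 FPKM in CTR and 1.68 in IM, and CCND3, cyclin D3, which overlaps another gene, had 6.72 and 3.25. Of 11 ERK targets, 8 lay below CTR (median -0.28, random range -0.16 to 0.28), led by the AP-1 subunit FOSL1 (3.21 and 1.06 FPKM), the transcription factor ETV4 (1.70 and 0.736) and the phosphatase DUSP5 (1.79 and 0.822). Both lists also lay below their random ranges in IM-DSF against DSF, at -0.31 and -0.41.

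Growth and cell cycle genes shifted together by less than the size rule. All but 1 of the 29 MYC targets of ribosome biogenesis were lower in IM (median -0.48, random range -0.22 to 0.08), among them RRP9, a component of nucleolar small ribonucleoproteins, at 0.517 times CTR (0.468 to 0.571), and UTP20, a ribosomal subunit processome protein, at 0.557 times (0.522 to 0.594). None of the 29 passed the size rule. Of 28 G1/S genes 26 were lower (median -0.39, range -0.22 to 0.07), including the replication factors MCM10 (10.5 and 6.07 FPKM) and MCM6 (102 and 70.1). Of 29 G2/M genes 27 were lower (median -0.36, range -0.20 to 0.07), including the mitotic kinases AURKA (20.48 and 11.3 FPKM) and PLK1 (13.0 and 7.99). In IM-DSF against DSF the 3 medians were -0.38, -0.48 and -0.33, each below its random range. Random lists of abundant genes themselves lay below 0: protein-coding genes with a mean of at least 20 FPKM had a median of -0.13 in IM against CTR. The matching on expression, planned beforehand, allows for this.

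Heat shock, ATF4, proteasome, endoplasmic reticulum chaperone and glycolysis lists were also lower with IM. Heat shock genes had a median of -0.58 (random range -0.24 to 0.14), with 17 of 18 below CTR, led by the collagen chaperone SERPINH1 (6.12 FPKM in CTR, 2.33 in IM), HSPH1 (21.8 and 11.7) and FKBP4 (59.95 and 35.4), both partners of the large chaperones. ATF4 targets had a median of -0.36 (range -0.17 to 0.13), and 20 of 28 were lower, including TRIB3, a pseudokinase induced by stress (11.4 and 3.69 FPKM), and the serine synthesis enzymes PSAT1 (69.1 and 38.0) and PHGDH (19.7 and 10.9). Proteasome subunits had a median of -0.37 (range -0.21 to 0.06), with 30 of 31 lower; PSMB6, a catalytic subunit, was at 0.457 times CTR (0.396 to 0.527). Endoplasmic reticulum chaperones had a median of -0.23 (range -0.21 to 0.14), with XBP1, a transcription factor of the unfolded protein response, at 19.0 and 8.39 FPKM. Glycolysis genes had a median of -0.29 (range -0.24 to 0.14), including PKM, pyruvate kinase (64.6 and 42.5 FPKM). The same 5 lists lay below their random ranges in IM-DSF against DSF, at -0.56, -0.25, -0.33, -0.26 and -0.25. There the endoplasmic reticulum list returned into range with genes of at least 5 FPKM (-0.27), and the glycolysis list in 3 of the alternative settings.

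Granulocyte and monocyte markers, lysosome genes and ribosomal proteins lay above their random ranges with IM. Of 19 granulocyte and monocyte markers 18 were higher in IM than in CTR and 4 passed the size rule (median 0.60, range -0.22 to 0.15); AZU1, the granule protein azurocidin, had 111 and 241 FPKM, and CSF1R, the receptor of the macrophage growth factor, had 0.434 and 1.94. Of 22 autophagy and lysosome genes 19 were higher and 0 passed the size rule (median 0.20, range -0.15 to 0.17), including the protease CTSB (10.04 and 16.8 FPKM, overlapping another gene). Ribosomal protein genes were higher in 48 of 50 cases (median 0.26, range -0.23 to 0.01), with RPS18 at 1.72 times CTR (1.68 to 1.76). In IM-DSF against DSF the 3 medians were 0.23, 0.35 and 0.06, each above its range. Ribosomal protein genes have many near-identical pseudogenes, and pseudogenes took up a large part of such families: RPLP0P6 had 542 FPKM in CTR where RPLP0 had 71.1.

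**Figure D2:**
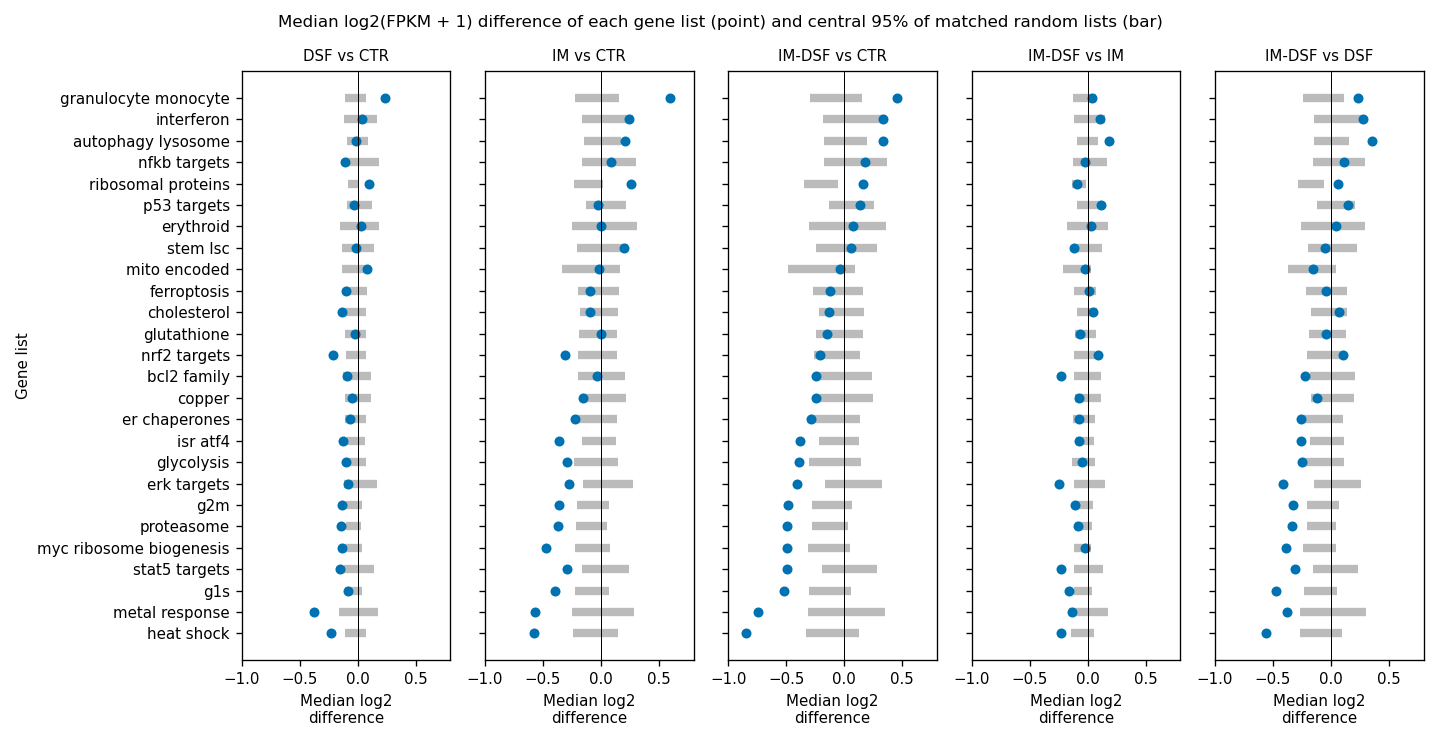
Median log2(FPKM + 1) difference (horizontal axis, log2 units) of each of 26 gene lists (vertical axis) in 5 contrasts between single libraries; points are list medians and grey bars the central 95% of 10000 expression-matched random lists. Heat shock lay at -0.84 and granulocyte and monocyte markers at 0.46 in IM-DSF against CTR.

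DSF against CTR asks what DSF alone left different, and IM-DSF against IM asks the same in cells that also received IM. Only a few genes were past the size rule in the same direction in both. YWHAB, a 14-3-3 adaptor protein, had 9.31 FPKM in CTR and 26.8 in DSF (2.87-fold, 2.68 to 3.08), and 11.6 in IM and 32.6 in IM-DSF (2.82-fold, 2.65 to 3.01). PRNP, the prion protein, was 2.52-fold higher in DSF (2.01 to 3.14) and 5.79-fold higher in IM-DSF than in IM (4.49 to 7.55). CAB39, a scaffold of the kinase LKB1 (5.94 and 14.7 FPKM in CTR and DSF), and RAB5C, an endosomal GTPase (6.13 and 17.01), were likewise higher, but both overlap another gene. The read-through gene ISY1-RAB43 was listed at 0 in CTR and IM and at 4.50 and 1.80 FPKM in DSF and IM-DSF.

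MKI67, the proliferation antigen Ki-67, was lower with DSF, at 24.5 FPKM in CTR and 10.99 in DSF (0.448 times, 0.426 to 0.473), and 27.8 in IM and 7.76 in IM-DSF (0.280 times, 0.263 to 0.297). It was the only 1 of 29 G2/M genes past the size rule in DSF against CTR, where their median was -0.13. In IM it was 1.13 times CTR (1.09 to 1.18), while 27 of the 29 were lower. The zinc finger gene ZKSCAN1 had 7.44 and 2.03 FPKM in CTR and DSF, ANKRD52, a phosphatase regulatory subunit, had 19.2 and 8.14, and GMFB, glia maturation factor beta, had 4.69 and 1.36. Overlapping genes among the 8 lower ones were ZNF551 (5.03 and 0.708 FPKM), LEPROTL1 (14.8 and 5.07), NDUFC2-KCTD14 (7.03 and 1.61) and CFAP298-TCP10L (1.22 FPKM in CTR, listed at 0 in DSF and IM-DSF). The size rule called 60 genes higher and 63 lower in DSF than in CTR, and 77 higher and 114 lower in IM-DSF than in IM. Of these, 6 were higher in both and 8 lower in both, where independent lists would share 0.420 and 0.653, while 15 went in opposite directions. Across genes the 2 contrasts correlated at r = 0.06 and rho = 0.14. Many protein-coding calls overlapped another gene on the same strand: 58 of 104 in DSF against CTR (55.8%) and 55 of 117 in IM-DSF against IM (47.0%). In the other contrasts the share was 38.0% (IM-DSF against CTR) to 42.3% (IM against CTR). Of all 9365 protein-coding genes past the filter, 6154 had no such overlap.

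As groups, several of the lists that were lower with IM were also lower in DSF than in CTR, by less; both contrasts use the same CTR library. Heat shock genes had a median of -0.23 (random range -0.11 to 0.07), with HSPH1 at 0.660 times (0.621 to 0.701) and HSP90AA1, the inducible HSP90, at 0.709 times CTR (0.693 to 0.725). STAT5 targets had a median of -0.15 (range -0.12 to 0.14), with PIM1 at 0.510 times (0.447 to 0.580) and CISH at 0.580 times (0.508 to 0.662). G2/M genes had a median of -0.13 (range -0.10 to 0.04), MYC targets -0.14 (range -0.10 to 0.04), proteasome subunits -0.14 (range -0.10 to 0.03) and ATF4 targets -0.13 (range -0.09 to 0.06). Granulocyte and monocyte markers were higher in 18 of 19 cases (median 0.24, range -0.11 to 0.08), with CSF3R at 5.003 FPKM in CTR and 9.50 in DSF. Ribosomal proteins had a median of 0.10 (range -0.09 to 0.01) and the 13 mitochondrially encoded genes 0.08 (range -0.13 to 0.07), led by MT-CO2, a cytochrome oxidase subunit, at 1.11 times CTR (1.10 to 1.12); the mitochondrial list returned into range with genes of at least 5 FPKM.

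In IM-DSF against IM, 6 lists lay below their random ranges and 2 above. Heat shock genes had a median of -0.23 in IM-DSF against IM (range -0.14 to 0.06), with 16 of 18 lower, including the cochaperone DNAJB1 (16.5 and 10.3 FPKM) and HSPB1 (143 and 98.5). STAT5 targets had a median of -0.23 (range -0.11 to 0.13), with PIM1 at 0.563 times IM (0.437 to 0.715), and ERK targets -0.25 (range -0.11 to 0.15), with the phosphatase DUSP6 at 3.92 and 2.94 FPKM. G1/S genes had a median of -0.16 (range -0.12 to 0.04), with the licensing factor CDT1 at 19.3 and 13.5 FPKM, and G2/M genes -0.11, which returned into range in 5 of the alternative settings. Autophagy and lysosome genes were higher in 19 of 22 cases (median 0.18, range -0.09 to 0.09), including MAP1LC3B, an autophagosome protein (1.70 and 4.27 FPKM). Heat shock, STAT5 and G2/M targets were the 3 lists below range in both DSF contrasts, where independent calls among the 26 lists would give 2.08.

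**Figure D3:**
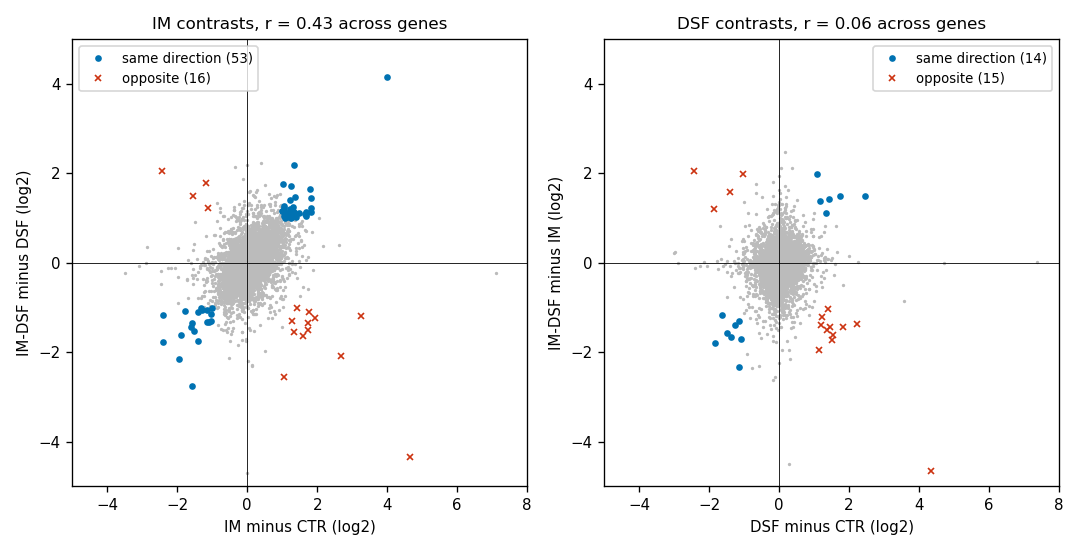
Log2(FPKM + 1) differences per gene in the 2 IM contrasts (left panel) and the 2 DSF contrasts (right panel), each pair sharing no library; each point is 1 of 11004 genes. Coloured symbols mark genes past the size rule in both: 53 in the same and 16 in opposite directions for IM, 14 and 15 for DSF.

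IM-DSF against CTR asks what the combination left different, and it held more called genes than either drug alone, with 279 higher and 192 lower. MS4A6A had 0.929 FPKM in CTR and 9.31 in IM-DSF, and OLR1, a scavenger receptor for oxidised LDL, had 0.568 and 5.58. The lysosomal genes DNASE2 and FUCA1 were 7.51-fold (5.68 to 9.93) and 4.76-fold (4.15 to 5.46) higher, TP53INP1 7.48-fold (6.06 to 9.40). ZNF117, GNG7, a G protein gamma subunit, AOAH and TIFAB were 5.40, 18.4, 7.44 and 4.84 times the CTR level, but all 4 overlap another gene. SLC16A1, the lactate transporter MCT1, was at 0.220 times CTR (0.194 to 0.248), with 21.8, 18.5, 15.2 and 4.80 FPKM in CTR, DSF, IM and IM-DSF. PIM1 was at 0.164 times (0.131 to 0.202). STON1, an endocytic adaptor (4.38 and 0.224 FPKM), and ZNF551 (5.03 and 0.424) were lower but overlap other genes.

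Several of the most different genes in this contrast were read-through genes, some with values that mirrored those of a neighbour. BLOC1S5-TXNDC5 was listed at 0 in CTR and had 139 FPKM in IM-DSF, while TXNDC5, a disulfide isomerase inside it, had 115 and 18.3. FMC1-LUC7L2 had 76.2 and 11.6 FPKM, and LUC7L2, which it contains, had 11.8 and 19.9. SENP3-EIF4A1 (29.6 and 2.17 FPKM) and STON1-GTF2A1L (4.36 FPKM and listed at 0) are read-through genes too. EIF4A1 went the other way from the former (10.95 and 14.9 FPKM), while SENP3 (11.6 and 7.76 FPKM) was lower along with it, as STON1 was with STON1-GTF2A1L. RN7SL1, the signal recognition particle RNA, appears under 2 gene identifiers, 1 at 6.43 FPKM in CTR and listed at 0 elsewhere and 1 at 7.61 FPKM in CTR and 0.537 in IM-DSF; it has many copies.

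GPX4-related and redox genes were mixed in IM-DSF. The 18 measured ferroptosis genes had a median of -0.12 (random range -0.27 to 0.16), and the list was within range in every contrast. In DSF against CTR, however, it lay below range in 3 of the alternative settings (-0.14 with a pseudocount of 0.1). The list joins defence and execution genes, which can move in opposite directions. Its median therefore cannot show whether a ferroptosis response was present or absent. SAT1, which acetylates polyamines, was the 1 member past the size rule, at 4.23 FPKM in CTR and 12.8 in IM-DSF (3.03-fold, 2.52 to 3.69), while SCD, a fatty acid desaturase, was at 0.562 times CTR (0.545 to 0.579). Glutathione genes had a median of -0.15 (range -0.25 to 0.16) and also stayed within range in every contrast, although GPX1, the cytosolic glutathione peroxidase, was 3.004-fold higher (2.80 to 3.23; 50.1 and 151 FPKM) and OPLAH, 5-oxoprolinase, 3.53-fold higher but overlapping another gene. Among NRF2 targets the peroxiredoxin PRDX1 was at 0.421 times CTR (0.395 to 0.448) and the quinone reductase NQO1 had 6.36 FPKM in CTR and 3.18 in IM-DSF (a ratio interval of 0.405 to 0.618), while BLVRB, a biliverdin reductase, was 3.43-fold higher (2.31 to 5.11). The NRF2 list was below range in DSF (-0.21) and in IM (-0.31) against CTR, but within it in IM-DSF against CTR (-0.21, range -0.26 to 0.14).

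Metal response genes were lower. Of 6 metal response genes all 6 lay below CTR in IM-DSF (median -0.74, range -0.31 to 0.35), among them the metallothioneins MT1E (16.3, 10.9, 9.83 and 5.98 FPKM in CTR, DSF, IM and IM-DSF), MT1G (8.67 and 4.28 in CTR and IM-DSF) and MT2A (6.44 and 3.87); metallothioneins are close paralogs, so the split between them is uncertain. The list was also below range in DSF (-0.38) and in IM (-0.57) against CTR. Copper handling genes had a median of -0.24 (range -0.21 to 0.25), with DLAT, a lipoylated pyruvate dehydrogenase subunit, at 0.492 times CTR (0.453 to 0.532) and SLC31A1, the copper importer, at 0.665 times (0.595 to 0.743); this list returned into range in 3 of the alternative settings.

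Except for the NRF2 targets, every list below range in IM against CTR was also below range in IM-DSF against CTR. The 2 contrasts use the same CTR library, so a deviation of CTR would place the same lists below range in both. The medians of MYC targets and ATF4 targets were nearly the same in both, and those of the MYC, ATF4, proteasome, endoplasmic reticulum, glycolysis and metal response lists were within range in IM-DSF against IM. Heat shock genes had a median of -0.84 (range -0.33 to 0.12), with 17 of 18 lower and 4 past the size rule, including HSP90AA1 (231 and 102 FPKM), HSPH1 (21.8 and 10.1) and the overlapping genes HSPE1 (91.2 and 36.9) and HSPA8 (134 and 61.8). STAT5 targets had a median of -0.50 (range -0.19 to 0.29), ERK targets -0.40 (range -0.16 to 0.32), G1/S genes -0.52 (range -0.30 to 0.06), G2/M genes -0.48 (range -0.28 to 0.06), MYC targets -0.49 (range -0.31 to 0.05) and proteasome subunits -0.49 (range -0.28 to 0.04). ATF4 targets had a median of -0.38 (range -0.22 to 0.12), with the glutamine transporter SLC1A5 at 77.2 and 30.01 FPKM and the mitochondrial folate enzyme MTHFD2 at 35.5 and 15.3. Glycolysis genes had a median of -0.39 (range -0.31 to 0.14). Endoplasmic reticulum chaperones had -0.29 (range -0.28 to 0.13), with XBP1 at 0.295 times CTR (0.253 to 0.344), but this list returned into range in 2 of the alternative settings. Granulocyte and monocyte markers had a median of 0.46 (range -0.29 to 0.15), with 16 of 19 higher and 6 past the size rule, including TYROBP, a signalling adaptor of myeloid receptors (2.86 and 8.88 FPKM), and the calcium-binding protein S100A9 (2.03 and 6.41). Autophagy and lysosome genes had a median of 0.34 (range -0.17 to 0.19), with 21 of 22 higher, including GABARAPL1, an autophagosome protein (2.40 and 5.56 FPKM). Ribosomal proteins had a median of 0.16 (range -0.35 to -0.06). Over all contrasts and the departure, 156 list medians were placed and 73 stood apart, 55 below and 18 above. Random lists of unrelated genes would give 7.8. That is no chance expectation for these lists, whose members can vary together. The 156 placements also reuse the same 4 libraries, and some lists share members.

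The departure from additivity asks whether the combination differed from the sum of the single drugs. By the size rule 152 genes lay above the sum and 185 below. SNX10, a sorting nexin of endosomes, had 9.64 FPKM in CTR, 3.04 in DSF, 3.70 in IM and 13.0 in IM-DSF, a departure of 2.97 log2 units. JRK, a DNA-binding protein, had 2.78, 0.182, 1.97 and 4.22 FPKM (2.49), and ZNF672, a zinc finger gene, had 1.59, 6.32, 6.78 and 1.37 (-3.22). ZNF664, FMC1-LUC7L2 and 1 row of RN7SL1 above the sum, and BIVM-ERCC5, BLOC1S5-TXNDC5, URGCP-MRPS24 and PMF1-BGLAP below it, all overlap other genes and are uncertain. Granulocyte and monocyte markers (-0.25), ribosomal proteins (-0.19) and stem cell genes (-0.24) lay below their random ranges in departure, and cholesterol (0.19), MYC targets (0.10) and autophagy and lysosome genes (0.14) above. A CTR library that was low for a list would raise both single-drug differences and lower the departure. With 1 CTR library this cannot be told apart from an effect of the drugs. The autophagy and lysosome list returned into range in 3 of the alternative settings. Of 221 protein-coding genes past the rule, 104 overlapped another gene on the same strand.

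In each of the 5 contrasts, at most 5 of the called genes with a known length had a counting interval that included 1, for example 1 of 123 in DSF against CTR and 4 of 468 in IM-DSF against CTR. Differences between cultures could not be measured with 1 library per group.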

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

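The tests of explanations in this part were chosen only after the result was seen. Among the named genes and the lists, a drug's effect was singled out where it went in opposite directions without and with the other drug. None of these differences was tested, since each group holds 1 library. The genes found were all named for their large departures from additivity, so a reversal was likely from the selection itself. The DSF and IM differences of a gene come from the same 4 values and are not separate results. On the log2(FPKM + 1) scale, the difference with DSF was -1.86 alone and 1.19 beside IM for the zinc finger gene ZNF664, -1.40 and 1.58 for SNX10, 1.501 and -1.72 for ZNF672, 1.82 and -1.43 for PMF1-BGLAP, and 4.35 and -4.66 for BIVM-ERCC5, which is listed at 0 in CTR and IM-DSF. The difference with IM was -1.55 alone and 1.503 beside DSF for ZNF664, -1.18 and 1.79 for SNX10, 1.59 and -1.63 for ZNF672, 1.75 and -1.502 for PMF1-BGLAP, 4.66 and -4.35 for BIVM-ERCC5, and 2.68 and -2.09 for URGCP-MRPS24, which is listed at 0 in IM-DSF. The median of the NRF2 targets was -0.21 with DSF alone and 0.09 beside IM, where it returned into range without a filter and when summed with pseudogenes.

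Genes that departed from additivity were more than counting noise gave. In 20 simulations with additive effects and counting noise alone, 24 to 43 genes departed by the size rule, against 335 seen among genes with a known length, which argues against counting noise as the only source. Reads moved between overlapping genes may account for a part: 47.1% of the 221 protein-coding departures overlapped another gene on the same strand (104 genes, 95% exact interval 40.3 to 53.9%). In expression-matched random lists the median was 34.8% and the upper limit 41.2%, so this cannot be excluded. Overlap on the opposite strand was not examined, and the use of strand in counting is not known. Genes without same-strand overlap are therefore not cleared of it either. BIVM-ERCC5 shows the pattern, at 0, 19.4, 24.2 and 0 FPKM in CTR, DSF, IM and IM-DSF where ERCC5 had 12.1, 6.02, 6.61 and 15.5. Each of the 221 was also assigned to the split with the smallest residual among those offered. These were each library alone, and CTR and IM-DSF against DSF and IM. The other pairings were not offered, and how well a split fitted was not assessed. For 58 genes the closest split set CTR and IM-DSF against DSF and IM. For the others it was necessarily a single library: CTR for 52, IM for 42, IM-DSF for 42 and DSF for 27. A true interaction of the drugs and differences between single cultures stay open, and without replicates neither was tested.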

How the results depend on the processing

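No paired analysis was possible because the labels give 1 library per group and no replicate numbers. With median-of-ratios and trimmed-mean factors all 18 counts stayed within 1.5 times their main values. Whether more genes were higher or lower depended on the setting in every comparison but IM against CTR. For DSF against CTR the balance turned with a pseudocount of 0.1 and without a filter (84 and 79), and for IM-DSF against CTR and against DSF with a mean of at least 5 FPKM. For IM-DSF against IM it turned among protein-coding genes without same-strand overlap, and for the departure both there and after rescaling to TPM. The restriction to protein-coding genes alone turned both (63 and 54, and 114 and 107), so these turns cannot be put down to overlap. The restriction by biotype and overlap and the sum with pseudogenes were chosen after seeing the data. Counts are given as higher and lower for DSF, IM and IM-DSF against CTR, IM-DSF against IM, IM-DSF against DSF and the departure, then as both higher, both lower and opposite for the DSF and the IM pair. With a pseudocount of 0.1 they were 168 and 141, 432 and 168, 576 and 318, 147 and 208, 317 and 223, 292 and 362, then 17, 19 and 29, and 114, 39 and 31. After rescaling to TPM, where a pseudocount of 1 weighs less and 14193 genes pass the filter, they were 300 and 300, 586 and 290, 906 and 468, 341 and 344, 603 and 344, 583 and 573, then 42, 40 and 82, and 157, 53 and 64. With a mean of at least 5 FPKM, where 5683 genes are left, they were 24 and 29, 70 and 44, 112 and 116, 24 and 65, 54 and 68, 57 and 75, then 4, 4 and 6, and 15, 12 and 8. Among the 6154 protein-coding genes without same-strand overlap they were 22 and 24, 67 and 45, 133 and 63, 36 and 26, 62 and 36, 62 and 55, then 2, 4 and 5, and 15, 10 and 6. Without a filter only the lower departures moved, to 292 of 22830 genes.

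Of the 73 list medians that stood apart, 61 did so in every setting that assessed them. Those that returned into range in at least 1 setting were the copper list in IM-DSF against CTR (-0.12 without a filter), the G2/M list in IM-DSF against IM (-0.06 after rescaling to TPM), the NRF2 list in IM-DSF against IM (0.01 when summed with pseudogenes), interferon genes in IM-DSF against DSF (0.07 without a filter), glycolysis in IM-DSF against DSF (-0.18 after rescaling to TPM), mitochondrially encoded genes in DSF against CTR (0.08 with a mean of at least 5 FPKM), the BCL2 list in 3 contrasts (-0.11 in IM-DSF against IM with a mean of at least 5 FPKM), endoplasmic reticulum chaperones in 2 and the lysosome list in the departure; the cause was not tested. Some of these calls were lost although the median did not shrink. With a mean of at least 5 FPKM the G2/M median was -0.11, as in the main setting. The copper median there was -0.34, against -0.24 in the main setting. Of the 83 medians within range, 72 stayed there in every setting that assessed them, and 11 left it in at least 1. These were ferroptosis genes (-0.15 after rescaling to TPM), NF-kB targets (-0.16 with a pseudocount of 0.1) and ERK targets (-0.08 without a filter), all below range in DSF against CTR. Ferroptosis genes and NRF2 targets were above range in the departure without a filter (0.10 and 0.09). Interferon genes were above range in IM-DSF against CTR in 5 settings (0.48 after rescaling to TPM) and in IM against CTR after rescaling to TPM (0.34). With a mean of at least 5 FPKM, NRF2 targets were above (0.15) and copper genes below range (-0.36) in IM-DSF against DSF, and ATF4 targets below it in IM-DSF against IM (-0.16). Summed with pseudogenes, ribosomal proteins were below range in IM-DSF against IM (-0.19). The depths of 12.4 M to 15.8 M fragments (M is 1e+06) limit genes near 1 FPKM most.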

Other observations

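The tests in this part were chosen only after the result was seen, except the test of a displaced CTR library. Of 12 measured apoptosis regulators of the BCL2 family, 10 were lower in IM-DSF than in CTR and 11 lower than in IM. BCL2L11, the proapoptotic BH3 protein BIM, had 3.99 FPKM in CTR, 1.64 in DSF, 7.32 in IM and 1.02 in IM-DSF, while BMF, another BH3 protein, had 3.07, 3.70, 6.82 and 8.40. PMAIP1, the BH3 protein NOXA, had 16.7 FPKM in CTR and 8.99 in IM-DSF, and BIK had 1.95 and 0.928. The list had a median of -0.24 in IM-DSF against CTR (random range -0.23 to 0.24) and -0.23 against IM (range -0.11 to 0.12), but both medians lay within range among genes of at least 5 FPKM, and the first also with a pseudocount of 0.1. BCL2L2, which overlaps another gene, had 0.396 FPKM in DSF and 5.32 to 5.76 in the other libraries. The 17 p53 targets stayed within range in every contrast (0.13 in IM-DSF against CTR), although MDM2, the ubiquitin ligase of p53, had 1.77, 1.26, 1.23 and 3.63 FPKM; it overlaps another gene.

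Cholesterol synthesis genes lay below range in DSF against CTR (median -0.13, range -0.10 to 0.07), with HMGCS1, the HMG-CoA synthase, at 15.7 FPKM in CTR and 11.1 in DSF. The median was nearly the same in IM-DSF against CTR (-0.13), but there the wider random range (-0.22 to 0.17) included it. SC5D, a sterol desaturase, was 3.17-fold higher in that contrast (2.62 to 3.87). The 9 NF-kB targets were within range in every contrast (0.18 in IM-DSF against CTR), but below it in DSF against CTR with a pseudocount of 0.1 (-0.16) and after rescaling to TPM (-0.19), while the cytokine TNF had 4.98, 2.19, 1.43 and 0.911 FPKM in CTR, DSF, IM and IM-DSF. The 10 interferon-stimulated genes had a median of 0.34 in IM-DSF against CTR, at the edge of their range (-0.18 to 0.34) and above it in 5 of the alternative settings, with the transcription factor STAT2, which overlaps another gene, at 4.53 and 10.3 FPKM. The 11 stem cell genes had a median of 0.06 in IM-DSF against CTR (range -0.24 to 0.28): IL1RAP, a surface protein of leukemia stem cells, had 2.78 and 1.79 FPKM, and CD47, a signal against phagocytosis, 8.97 and 13.8. The 6 erythroid genes had a median of 0.07 (range -0.31 to 0.36). Other lineages and histones were too low to assess, with 1 megakaryocyte marker, 1 lymphoid marker and 2 histones past the filter; these were GP1BB, at 1.24 FPKM in CTR, NKG7, at 11.4, and H1-2 and H2AC17, at 4.72 and 1.40.

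The differences DSF minus CTR and IM minus CTR had a covariance of 0.0694 across 9365 protein-coding genes. Simulated unchanged libraries against the same CTR gave 0.0045 from counting noise. Noise of the shared CTR library raises this covariance. That of DSF minus CTR with IM-DSF minus DSF, which noise of the DSF library lowers and noise of CTR leaves alone, was -0.0064 (jackknife standard error over chromosomes 0.0039); their mean was 0.0315. The corresponding mean for IM-DSF minus IM, which does not use CTR and was predicted to be at or under 0 if only CTR were displaced, was 0.0220 (standard error 0.0011), from -0.0140 and 0.0580. The bound set beforehand, a mean above 0 by over 2 standard errors, was wrong by design. IM-DSF enters both differences behind the 0.0580, so its own deviation, which 1 library does not measure, raises that value with or without a displaced CTR. The covariance with IM minus CTR, in which IM-DSF is in only 1 of the differences, was -0.0140 (standard error 0.0033), not above 0, although noise of the IM library lowers it. A weak IM-like effect of DSF, which may be biological, and a noisy or displaced CTR library therefore cannot be told apart.

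Genes past the size rule in both contrasts of a drug were split by whether their 2 differences had the same direction. For IM, 53 of 69 such genes, 76.8% (95% exact interval 65.1 to 86.1%), had the same direction. Genes that vary independently between any 2 libraries would go the same way about as often as in opposite ways. The interval treats genes as independent, which they are not. Genes that vary together between cultures could also give a high share, so such variation is not excluded for IM. For DSF the share was 48.3% (14 of 29; 29.4 to 67.5%), which is what such variable genes would give, so the DSF genes named in the report, MKI67 among them, may be of this kind. An effect of DSF that reverses with IM is the biological alternative and was not tested apart from this. The difference between the shares of the drugs was not tested.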
